A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

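Polyadenylated RNA of budding yeast was sequenced from 4 strains of the BY4742 background with 2 libraries each: the wild type (WT), a strain without RRP6, a strain without AIR1 and RRP6, and a strain without AIR2 and RRP6. Per the labels' protocols, each strain was grown from a colony in rich medium at 30 °C to an optical density of about 2.5, total RNA was extracted with phenol and chloroform, RNA with a poly(A) tail was bound to poly(U) sepharose, and libraries were prepared for SOLiD sequencing. The labels do not say whether the duplicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

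The count table deposited by the authors holds an expected count per feature and library, with no scaling for depth. Between 11.1 and 13.0% of its values per library are not whole numbers. This can arise when reads with several matches are shared between features, though the labels do not say how such reads were counted. Per the submitters' processing notes, Bowtie 0.12.7, SAMtools and edgeR 2.2.5 were used, with no roles or settings given. The genome build and the annotation are not given in the sources used here, so no coordinates are reported. Per the file headers, a second table deposited by the authors holds a log2 ratio and a p-value per feature for 5 of the comparisons. That table was set beside the fits below and entered none of them. Its rrp6 p-value column has 1 value below 0, and that entry was not used.

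The count table has 9014 features, among them 925 cryptic unstable transcripts (CUTs), 847 stable unannotated transcripts (SUTs), 76 small nucleolar RNAs and 25 features of the ribosomal DNA. Of the feature identifiers, 6048 matched a RefSeq table of yeast genes, and 5362 of these had a symbol. No column was left out. Whether counting followed strand could not be settled. The 37 dubious reading frames that lie opposite a gene had a median count of 0.174% of that gene's count. The 1 such frame on the same strand as its gene had 0.00818%, so low counts do not show that strand was used. Total counts ran from 13787609 in WT replicate 1 to 124620247 in WT replicate 2. The ribosomal DNA features held 51.7 to 82.3% of each library. Counts outside these features ran from 4565468 to 22041136.

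Duplicates of each strain were compared first. They differed by far more than counting error, with a chi-square per degree of freedom of 56.2 in WT, 96.9 in the rrp6 strain, 35.8 in the air1 rrp6 strain and 53.9 in the air2 rrp6 strain, so no library repeats another. Counting intervals and floors below cover counting error only. A floor is 3 counts over the whole group, and a ratio to a group with 1 to 3 counts carries its exact 95% interval.

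Expected counts were rounded to whole numbers. Features were kept by filterByExpr of edgeR 4.0.16 with its minimum count of 10, libraries were scaled by trimmed mean of M-values (TMM), and a robust quasi-likelihood model with 1 mean per strain was fitted to all 8 libraries in R 4.3.3. The 4 strains therefore shared an estimate of the spread, since duplicates alone leave few degrees of freedom. Of the features, 7543 were tested in each of 6 comparisons, and adjusted p-values are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over these features, with a threshold of 0.05. Values given per gene are edgeR's scaled counts (CPM) on the TMM scale as mean ± SD over 2 libraries, and standard errors (SE) belong to the log2 fold change. An exact test of 2 libraries against 2 cannot give a p-value below 0.33, and shares of counts were compared without a test.

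Before the data were examined, the comparisons, the tests, 48 gene lists and a rule for the genes named in the text were fixed. The rule took, per comparison, the 8 largest changes in each direction among features past the threshold with at least 5 CPM in the higher strain and no overlap between libraries. It added the deleted genes, the LEU2 marker, and up to 4 members with the smallest adjusted p of each list that passed its test or had at least 3 members past the threshold. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of each comparison. They were also tested with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Counts of members were taken over all features tested and adjusted over the list alone. One feature that met the rule is not reported here.

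Replicate numbers are shared by the strains. Deviations of the same-numbered libraries from their strain means correlated in all 6 pairs of strains, at 0.13 to 0.37 across features, so the numbers may mark a pairing. The model without the replicate as a block stayed the reported one, since no label says that the numbers mark a batch, and the blocked value stands beside a result where it changes the call or moves a count of calls by over 1.5 times.

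The alternatives tried were DESeq2 size factors, library totals without TMM, TMM from protein-coding genes, DESeq2 1.42.0, the edgeR exact test, limma-voom, 2 other count filters, the legacy and the non-robust quasi-likelihood model, fits of the 2 strains compared, the replicate block, an adjusted p under 0.01, a minimum fold of 2, and leaving out each library. Alternatives chosen after seeing the data were WT replicate 2 thinned to the depth of WT replicate 1, a fit without ribosomal DNA features, and the ribosomal DNA share of the library as a covariate. Where comparisons shared libraries, counts for all 8 libraries were simulated 20 times without any change between strains. Means were those of the rrp6 libraries, and depths were those of each library.

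The model was tested on simulated counts for the comparison of the rrp6 strain with WT, with 200 changed features among 7375 to 7450 in each of 20 draws. The changed features were drawn from those with a mean of at least 5 CPM and moved up or down at random. The model recovered on average 29.5% of 2-fold (14 to 44% over the draws), 94.8% of 4-fold, 99.5% of 8-fold and 99.1% of 16-fold changes. Recovery of changes in features below that mean was not tested. Of 3464 calls over all draws, 235 or 6.78% were false, with 5 to 20 in a draw, and at most 2 calls were made in a draw between groups where nothing had changed. Tables and plots were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.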

Results

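The abundance of polyadenylated RNA was measured by SOLiD sequencing in 4 strains of budding yeast, each with 2 libraries. The strains were WT, a strain without RRP6 (rrp6), a strain without AIR1 and RRP6 (air1 rrp6) and a strain without AIR2 and RRP6 (air2 rrp6). RRP6 encodes the nuclear exonuclease subunit of the RNA exosome, and AIR1 and AIR2 encode zinc knuckle proteins of the TRAMP complex, which adds short adenosine tails to RNAs for degradation by the exosome. The series asks whether Air1 and Air2 direct TRAMP to different RNAs. Total counts in replicates 1 and 2 were 13787609 and 124620247 in WT, 28895762 and 25803409 in rrp6, 20720755 and 16087567 in air1 rrp6, and 29750702 and 18742328 in air2 rrp6. Features of the ribosomal DNA took most of them, and counts outside these features were 4565468 and 22041136 in WT, 12437479 and 8029375 in rrp6, 6054090 and 7770018 in air1 rrp6, and 12763854 and 8420157 in air2 rrp6. The first principal component of the tested features, with 59.6% of the variance, placed both WT libraries apart from the 6 libraries without RRP6.

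The deleted genes matched the labels in every library. RRP6 had 377 and 2131 counts in the WT libraries, and 19 to 51 counts in each of the 6 libraries labelled as lacking it. AIR1 had 7 and 2 counts in the air1 rrp6 libraries and 210 to 1212 in the others. AIR2 had 34 and 21 counts in the air2 rrp6 libraries and 102 to 549 in the others. LEU2, which encodes isopropylmalate dehydrogenase and is deleted in BY4742, had 0 counts in both WT libraries and 219 to 559 counts in each library without RRP6. LEU2 was at least 267-fold higher in each strain without RRP6 than the floor of 3 counts over the WT libraries. LYS2 and URA3, both deleted in the background strain, had 0 counts in all 8 libraries. HIS3, a further gene of the same fixed list of deleted genes and markers, had 158 to 509 counts in each library.

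RNA classes took different shares of the libraries. Of the counts outside rRNA and mitochondrial features, CUTs held 0.0639% ± 0.017 (SD, n = 2) in WT, 0.522% ± 0.056 in rrp6, 0.426% ± 0.047 in air1 rrp6 and 0.497% ± 0.067 in air2 rrp6. SUTs held 0.274% in WT, 0.541% in rrp6, 0.524% in air1 rrp6 and 0.553% in air2 rrp6. Small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA, held 1.99% ± 1.1 in WT, 3.29% ± 0.1 in rrp6, 2.51% ± 0.44 in air1 rrp6 and 1.83% ± 0.18 in air2 rrp6. These shares were not tested, and an exact test of 2 libraries against 2 allows no p-value below 0.33.

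**Figure D1:**
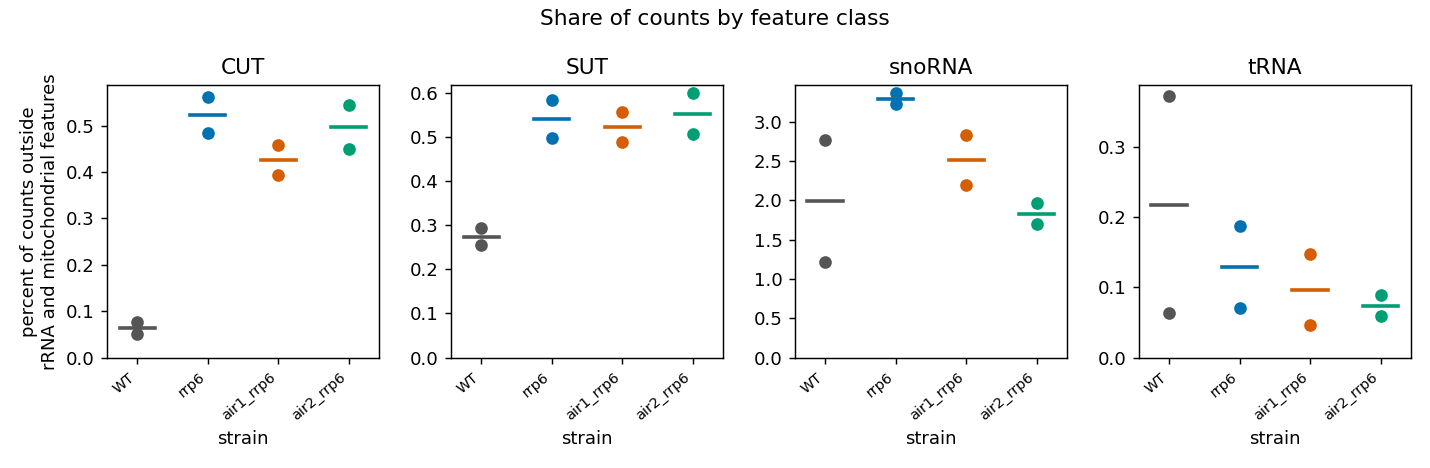
Share of each library's counts outside rRNA and mitochondrial features, in percent, held by CUTs, SUTs, snoRNAs and tRNAs in the 4 strains. Points are libraries and lines are means, and the CUT share was 0.0639% in WT and 0.426 to 0.522% in the strains without RRP6.

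The first comparison, rrp6 against WT, asks which RNAs differ when Rrp6 is absent. Every library without RRP6 also holds LEU2 reads, which both WT libraries lack. Comparisons with WT therefore cannot tell the loss of RRP6 from the presence of LEU2. CUTs, short noncoding RNAs that the nuclear exosome degrades soon after synthesis, rose as a class. Of 759 CUTs tested, 455 were higher, or 611 adjusted over the list alone, and the median log2 fold change of the class was 2.91. CUT222 rose from 0.196 ± 0.049 to 31.4 ± 3.2 CPM, a log2 fold change of 7.20 (SE 0.28, n = 2, adjusted p = 4e-06). CUT306 rose from 3.78 ± 1.1 to 252 ± 57 CPM (log2 fold change 6.04, adjusted p = 3.8e-05) and CUT841 rose by 6.67 (adjusted p = 8.1e-05). CUT350 had 2 counts over both WT libraries and 411 over both rrp6 libraries, a ratio of 258 with a counting interval of 71 to 2140. SUTs, noncoding RNAs that are stable enough to be seen in WT cells, had a smaller shift: 123 of 687 were higher and 1 was lower, or 164 and 1 adjusted over the list alone, with a median of 0.86. SUT720 rose by 3.50 (adjusted p = 0.00073) and SUT279 by 3.86 (adjusted p = 0.0012). Both classes ranked above other features by camera (adjusted p = 3.7e-113 for CUTs and 5.9e-11 for SUTs). With a correlation estimated from the data neither passed (adjusted p = 0.087 with an estimated correlation for CUTs, and 0.39 for SUTs). The count of higher SUTs was 65 without rrp6 replicate 1, 70 without WT replicate 1 and 245 with library totals, where their median was 1.60. With the ribosomal DNA share as a covariate 218 CUTs and 44 SUTs were higher, at medians of 3.03 and 0.96, and with the 2 strains fitted alone 240 and 37.

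**Figure D2:**
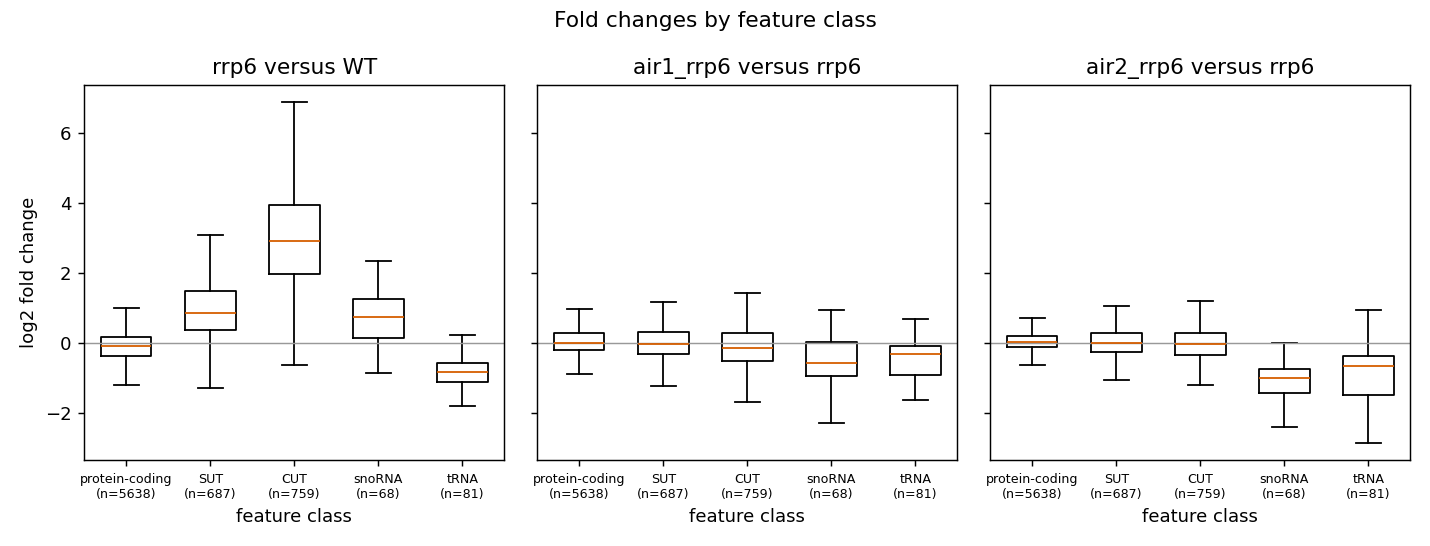
Log2 fold changes of protein-coding genes (n = 5638), SUTs (687), CUTs (759), snoRNAs (68) and tRNAs (81) in rrp6 against WT and in each double mutant against rrp6. Boxes are quartiles, whiskers reach 1.5 interquartile ranges and more distant features are not drawn; the CUT box stands at a median of 2.91 in rrp6 against WT and at -0.15 and -0.02 in the double mutants.

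Among snoRNAs of the box C/D type, which guide methylation, 4 of 41 rose in rrp6, the same count as adjusted over the list alone. SNR68 rose by 2.23 (adjusted p = 0.005), SNR53 by 3.17 (adjusted p = 0.0061), SNR58 by 2.18 (adjusted p = 0.0092) and SNR4 by 2.34 (adjusted p = 0.012). The SNR58 call was lost without rrp6 replicate 1, the SNR4 call without rrp6 replicate 1 or WT replicate 1, and the SNR53 call with the ribosomal DNA share as a covariate (their adjusted p ran up to 0.053, 0.058 and 0.056 over all alternatives). The list had a median of 0.80 and ranked above other features by camera (adjusted p = 0.0013), which did not hold with an estimated correlation (adjusted p = 0.96 with an estimated correlation). Single libraries decided this group: without WT replicate 1 the median was 0.27, 3 members were higher and the camera call ended, without WT replicate 2 the median was 1.63, over left-out libraries camera's adjusted p ran from 2.3e-14 to 0.32, and the higher members numbered 18 without WT replicate 2, 2 without rrp6 replicate 1 and 7 without rrp6 replicate 2.

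Protein-coding genes moved less: 58 of 5638 were higher in rrp6 and 99 lower, or 77 and 73 with TMM from protein-coding genes. GYP5, which encodes a GTPase-activating protein for Rab proteins, fell from 15.4 ± 3.7 to 0.515 ± 0.13 CPM (log2 fold change -4.87, SE 0.50, n = 2, adjusted p = 0.00083). HFM1, a meiotic DNA helicase gene, fell by 3.98 (adjusted p = 0.0031), and GRX4, which encodes a glutaredoxin of iron signalling, fell by 2.98 (adjusted p = 0.0031). NRD1, which encodes an RNA-binding protein of noncoding transcription termination and lies outside the naming rule in this comparison, was chosen after its values were seen and rose by 2.39 (adjusted p = 0.0033). The coding count varied over left-out libraries, also over those of the double mutants. The latter enter this comparison only through the filter, the scaling and the shared estimate of the spread. The median of protein-coding genes was -0.10, and it ran from -0.17 to -0.09 over left-out libraries. The lower genes numbered 51 without WT replicate 1, 26 without rrp6 replicate 1, 292 without rrp6 replicate 2, 62 without air1 rrp6 replicate 2, 56 without air2 rrp6 replicate 1, 57 without air2 rrp6 replicate 2, and 179 with the replicate block, and 18 with library totals. The higher genes numbered 26 without WT replicate 1, 22 without rrp6 replicate 1, 34 without air1 rrp6 replicate 1, 33 without air2 rrp6 replicate 1, 35 without air2 rrp6 replicate 2, 90 with the replicate block, and 124 with library totals. With the ribosomal DNA share as a covariate 16 were higher and 25 lower, with the 2 strains fitted alone 13 and 25, and with the edgeR exact test 94 and 168.

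Leucine biosynthesis genes were among the genes that fell. LEU1, isopropylmalate isomerase, fell from 427 ± 46 to 73.4 ± 7.7 CPM (log2 fold change -2.54, SE 0.22, n = 2, adjusted p = 0.00044). OAC1, a mitochondrial carrier that also exports isopropylmalate, fell by 2.31 (adjusted p = 0.00064), BAT1, the mitochondrial branched-chain aminotransferase, fell by 2.27 (adjusted p = 0.00091), and ILV3, dihydroxyacid dehydratase, fell by 1.08 (adjusted p = 0.013). These were the 4 lower members of the 10 tested, or 5 adjusted over the list alone, and the ILV3 call was lost without rrp6 replicate 1, with library totals, with the ribosomal DNA share as a covariate and with the 2 strains fitted alone (its adjusted p ran up to 0.6 over all alternatives). The list ranked below other features by camera (adjusted p = 1.3e-07; adjusted p = 0.09 with an estimated correlation), and its median of -0.52 was 0.09 when libraries were scaled by their totals, a scaling that moved the median of all features to 0.64. Genes of the phosphate (PHO) regulon, induced when phosphate is scarce, followed: 4 of 18 were lower, or 7 adjusted over the list alone, with PHO5, an acid phosphatase, at -3.37 (adjusted p = 0.0055), PHO12 at -1.20 (adjusted p = 0.0038), PHO8 at -1.08 (adjusted p = 0.028) and PHO11 at -1.24 (adjusted p = 0.037). PHO11 and PHO12 are near-identical and PHO5 is related to them, so their separate values are uncertain. The PHO8 call was lost without either WT library or either rrp6 library, and the PHO11 call without WT replicate 2, rrp6 replicate 1, air1 rrp6 replicate 1 or air1 rrp6 replicate 2 (their adjusted p ran up to 0.61 and 0.58 over all alternatives). Both were also lost with library totals, with that covariate and with the 2 strains fitted alone, PHO11 with TMM from protein-coding genes, and PHO12 with library totals. The PHO list had a median of -0.46, or 0.06 with library totals, and passed camera (adjusted p = 0.00068) but not with an estimated correlation (adjusted p = 0.39 with an estimated correlation). Its lower members numbered 2 without WT replicate 2, 2 without rrp6 replicate 1 and 1 with library totals.

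In all, 678 of 7543 features were higher in rrp6 than in WT and 101 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1782 had an unadjusted p under 0.05 where 377 would by chance. With library totals in place of TMM, 1126 were higher and 19 lower, a share of 98.3% higher in place of 87.0%. The lower count was 63 without WT replicate 1, 28 without rrp6 replicate 1, 296 without rrp6 replicate 2, 63 without air1 rrp6 replicate 2, 57 without air2 rrp6 replicate 1, 58 without air2 rrp6 replicate 2, and 183 with the replicate block.

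The air1 rrp6 strain was compared with WT to see the same classes with Air1 also absent. CUTs rose again, with 410 of 759 higher, 607 adjusted over the list alone, and a median of 2.72. CUT222 reached 18.8 ± 2 CPM (log2 fold change 6.46, SE 0.27, n = 2, adjusted p = 8.7e-06) and CUT306 reached 112 ± 7.3 CPM (4.87, adjusted p = 0.0001). Of 687 SUTs, 94 were higher, 132 adjusted over the list alone, with a median of 0.83. GYP5 fell by 4.95 (adjusted p = 0.0011), and features of the 2-micron plasmid were lower, with a median of -6.64 over the list. LEU1 fell by 2.57 (adjusted p = 0.00041), OAC1 fell by 2.26 (adjusted p = 0.00072) and BAT1 fell by 1.58 (adjusted p = 0.0051), the 3 lower members of the leucine list, or 5 adjusted over the list alone. That list had a median of -0.63, or 0.08 with library totals, where the BAT1 call ended, as it did with the ribosomal DNA share as a covariate (camera adjusted p = 2.8e-07; adjusted p = 0.068 with an estimated correlation). CUTs passed camera (adjusted p = 1.8e-116) and also with an estimated correlation (0.045), though not in the model with the replicate block (0.13), and SUTs passed only the former (adjusted p = 1.3e-11; adjusted p = 0.29 with an estimated correlation). In total 585 features were higher and 59 lower, or 1165 and 15 with library totals. The higher count was 381 without WT replicate 2, 274 without air1 rrp6 replicate 1 and 204 without air1 rrp6 replicate 2, and the lower count was 22 and 19 without those air1 rrp6 libraries, 33 and 34 without air2 rrp6 replicates 1 and 2, and 126 with the replicate block. Higher CUTs numbered 252 without WT replicate 2, 221 without air1 rrp6 replicate 1 and 151 without air1 rrp6 replicate 2, and higher SUTs 49 without WT replicate 1, 26 and 24 without those air1 rrp6 libraries, 61 without air2 rrp6 replicate 1, and 141 with the replicate block. Higher CUTs and SUTs numbered 79 and 12 with the ribosomal DNA share as a covariate, at medians of 2.90 and 0.95, 655 and 259 with library totals, and 176 and 33 with the 2 strains fitted alone.

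The air2 rrp6 strain was compared with WT in the same way. CUTs rose, with 450 of 759 higher, 625 adjusted over the list alone, and a median of 2.87, and CUT222 reached 28.8 ± 0.38 CPM (log2 fold change 7.08, SE 0.28, n = 2, adjusted p = 4.5e-06). Of 687 SUTs, 115 were higher and 1 lower, or 141 and 1 adjusted over the list alone, with a median of 0.86. NRD1 rose by 2.48 (adjusted p = 0.003) and GSC2, a cell wall glucan synthase gene, by 1.63 (adjusted p = 0.0038). LIN1 fell by 4.27 (adjusted p = 0.0017), GYP5 fell by 5.91 (adjusted p = 0.00065) and PHO5 fell by 3.26 (adjusted p = 0.0061). The GSC2 and PHO5 calls ended with the ribosomal DNA share as a covariate (adjusted p = 0.089 and 0.058). Over all alternatives their log2 fold changes ran from 1.31 to 2.45 for GSC2 and from -3.50 to -2.41 for PHO5. LEU1 fell by 2.46 (adjusted p = 0.00057), OAC1 fell by 2.10 (adjusted p = 0.00083) and BAT1 fell by 2.0 (adjusted p = 0.0015). ILV3 fell by 0.91 (adjusted p = 0.026), a call that also ended without WT replicate 1, air2 rrp6 replicate 1 or air2 rrp6 replicate 2 and with that covariate. The leucine list had 4 of 10 members lower, the same adjusted over the list alone, and a median of -0.43 (camera adjusted p = 5.3e-07, or 0.11 with an estimated correlation). With library totals the list median was 0.46, the BAT1, OAC1 and ILV3 calls ended and LEU1 alone stayed. Over all alternatives the log2 fold change ran from -2.13 to -1.12 for BAT1, -2.31 to -1.23 for OAC1 and -1.07 to -0.04 for ILV3. Both noncoding classes passed camera (adjusted p = 5.8e-112 for CUTs and 1.8e-10 for SUTs), but not with an estimated correlation (adjusted p = 0.094 with an estimated correlation for CUTs, and 0.39 for SUTs).

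Against WT, 678 features were higher in air2 rrp6 and 118 lower, or 1522 and 22 with library totals, a share of 98.6% higher in place of 85.2%. The median of all features moved to 0.95 with that scaling, and to 0.78 in air1 rrp6 against WT. The higher count was 299 without air2 rrp6 replicate 2 and 428 without air2 rrp6 replicate 1, and the lower count was 37 and 43 without air2 rrp6 replicates 2 and 1, and 197 with the replicate block. Without air2 rrp6 replicate 2 the higher CUTs numbered 222 and the higher SUTs 35, and without air2 rrp6 replicate 1 the higher SUTs numbered 61. Higher CUTs and SUTs numbered 51 and 11 with the ribosomal DNA share as a covariate, at medians of 3.09 and 0.98, 699 and 358 with library totals, and 293 and 58 with the 2 strains fitted alone.

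The calls against WT overlapped. Of the higher features, 520 were shared by rrp6 and air1 rrp6, 582 by rrp6 and air2 rrp6, and 487 by all 3 strains without RRP6, where independent lists would share 52.6 and 60.9 in the pairs. Of the lower features, 32 and 66 were shared in these pairs, against 0.8 and 1.6 for independent lists, and 30 in all 3. Counts simulated for all strains from the rrp6 means, without any change, shared at most 2 calls over 20 simulations. Such simulations make few calls, so they do not measure how far shared WT libraries raise the overlap of real calls. The 2 WT libraries were not split, which would leave 1 library to each comparison, so part of the excess may come from the shared controls.

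Air1 rrp6 was compared with rrp6 to see what the loss of Air1 adds. Features of the 2-micron plasmid, a circular plasmid carried by most laboratory yeast strains, were lower in air1 rrp6. R0020C (REP1, plasmid partitioning) fell from 58.5 ± 7.6 to 0.594 ± 0.35 CPM (log2 fold change -6.58, SE 0.41, n = 2, adjusted p = 0.00017). R0040C (REP2) fell by 6.71 (adjusted p = 0.0007) and R0010W (FLP1, the plasmid's recombinase) fell by 6.81 (adjusted p = 0.0073). The list passed camera (adjusted p = 2.7e-115) and the test with an estimated correlation (0.00088). The R0010W call did not hold with the replicate block (adjusted p = 0.31, where its adjusted p ran from 3.1e-46 to 0.31 over all alternatives), nor without rrp6 replicate 1 or rrp6 replicate 2. The log2 fold change of R0010W ran from -9.15 to -5.83 over all alternatives. AIR1 itself was also lower (log2 fold change -6.45, adjusted p = 0.0007).

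**Figure D3:**
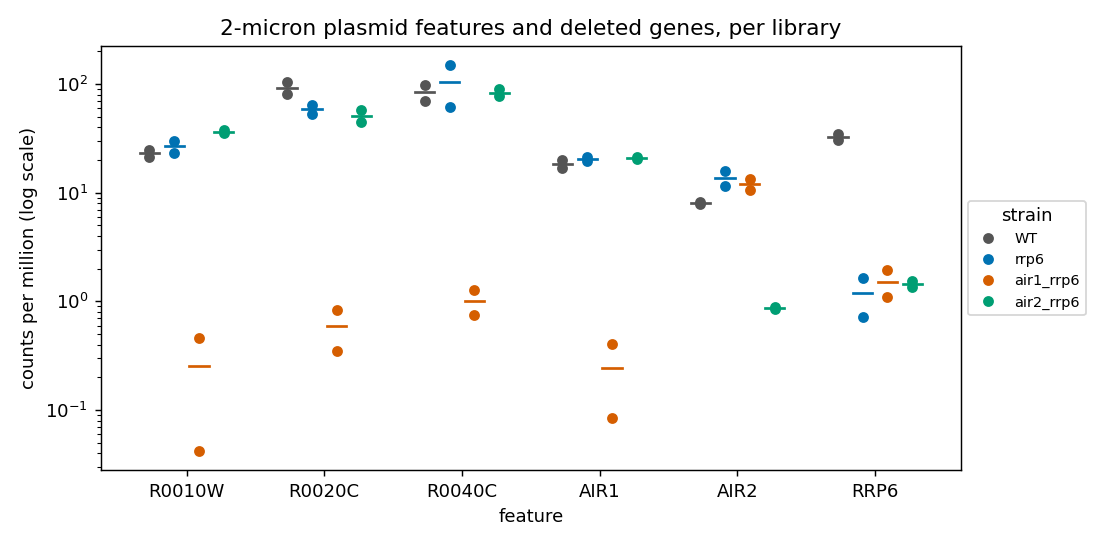
CPM on a log axis for the 2-micron plasmid features R0010W, R0020C and R0040C and the genes AIR1, AIR2 and RRP6 in the 4 strains. Points are libraries and lines are means, and the plasmid features had means of 0.252 to 1.01 CPM in air1 rrp6 against 26.7 to 106 CPM in rrp6.

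Over all features, edgeR's quasi-likelihood test called 0 higher and 5 lower in air1 rrp6 than in rrp6, with 441 features at an unadjusted p under 0.05 in either direction where 377 would be by chance. DESeq2 called 3 higher and 9 lower, and the edgeR exact test 2 and 8. The higher count was 12 without rrp6 replicate 2, and 1 without WT replicate 1 or WT replicate 2. Box C/D snoRNAs had a median of -0.81 and ranked below other features (camera adjusted p = 3.3e-13; adjusted p = 0.55 with an estimated correlation), with SNR53 at -2.30 (adjusted p = 0.77). Genes of cytosolic ribosomal proteins, many of them in near-identical pairs, had a median of 0.26 (camera adjusted p = 3.1e-06; adjusted p = 0.9 with an estimated correlation). Nuclear genes of the respiratory chain had a median of 0.45 (camera adjusted p = 2.8e-05; adjusted p = 0.55 with an estimated correlation). Without rrp6 replicate 1 the ribosomal protein median was 0.14 and the respiratory median 0.23, and the latter was 0.29 without air1 rrp6 replicate 2. No member of these 3 lists passed the test for single features, over all features or adjusted over the list alone. CUTs had a median of -0.15, or 0.02 with library totals, and their camera call (adjusted p = 0.033; adjusted p = 0.96 with an estimated correlation) ended without rrp6 replicate 2, where the median was 0.08, and without air1 rrp6 replicate 1, where it was -0.10 (camera's adjusted p ran from 7e-06 to 0.68 over left-out libraries).

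Air2 rrp6 was compared with rrp6 to see what the loss of Air2 adds. Box C/D snoRNAs had a median log2 fold change of -1.16 over 41 members, and 23 were lower when adjusted over the list alone. SNR53 stood at 9.4 ± 4.4 against 56 ± 37 CPM (log2 fold change -2.58, SE 0.49, n = 2) and SNR58 at 37.9 ± 9.2 against 145 ± 35 CPM (-1.94, SE 0.39), each with an adjusted p of 0.92 over all features. Box H/ACA snoRNAs, which guide pseudouridylation, had a median of -0.88 over 27 members, with 4 lower adjusted over the list alone, among them SNR49 at -1.69 (adjusted p = 0.92 over all features). The box H/ACA median was -0.47 without rrp6 replicate 2, -0.53 with library totals and -0.54 with the ribosomal DNA share as a covariate. Library totals moved the median of all features to 0.32 here, so list medians with that scaling are to be read against this value. Both lists ranked below other features by camera (adjusted p = 1.2e-54 for box C/D and 2.7e-17 for box H/ACA), but not with an estimated correlation (adjusted p = 0.31 with an estimated correlation for box C/D, and 0.49 for box H/ACA). Other structured RNAs ranked lower as well: spliceosomal snRNAs had a median of -0.90 over 6 members, all negative (camera adjusted p = 5.2e-05; adjusted p = 0.49 with an estimated correlation), and 4 further structured RNAs a median of -0.73, all negative (camera adjusted p = 0.0095; adjusted p = 0.61 with an estimated correlation). No member of either passed the test. Without rrp6 replicate 2 both camera calls ended, at medians of -0.48 and 0.04, and the second also ended without air2 rrp6 replicate 1, and with library totals the medians were -0.52 and -0.37. The rRNA features, transcribed without poly(A) tails, had a median of -0.52 (camera adjusted p = 1.8e-09; adjusted p = 0.6 with an estimated correlation), or -0.83 without rrp6 replicate 1, -0.17 with library totals and -0.18 with that covariate. Ty element genes, a repeated family whose reads may be shared between copies, had a median of 0.31 (camera adjusted p = 4.2e-05, or 0.62 with an estimated correlation). Adjusted over the list alone, 1 member was higher. The Ty median was 0.60 with library totals and 0.20 with that covariate.

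Over all features, edgeR's quasi-likelihood test called 0 features higher and 1 lower in air2 rrp6 than in rrp6, with 203 at an unadjusted p under 0.05 where 377 would be by chance. The lower one was AIR2 (log2 fold change -3.97, adjusted p = 0.00099), and this call ended without air2 rrp6 replicate 1 or air2 rrp6 replicate 2. Over all alternatives its log2 fold change ran from -4.18 to -3.70 and its adjusted p from 1e-24 to 0.065, the highest being those without these libraries. DESeq2 called 1 feature higher and 20 lower, 12 of the latter box C/D snoRNAs, and the edgeR exact test called 1 and 7. Library totals moved the median of all features to 0.32 in this comparison and to 0.12 in air1 rrp6 against rrp6.

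The double mutants were compared with each other, which tests whether the effects of losing Air1 and Air2 differ. AIR2 was higher in air1 rrp6 (log2 fold change 3.77, SE 0.28, n = 2, adjusted p = 0.00048) and AIR1 lower (-6.48, adjusted p = 0.00054). R0020C at -6.39 (adjusted p = 0.00021), R0040C at -6.37 (adjusted p = 0.00077) and R0010W at -7.26 (adjusted p = 0.0041) were also lower. The R0010W call ended with the replicate block (adjusted p = 0.11, range over alternatives 1.2e-52 to 0.11), with the 2 strains fitted alone and without rrp6 replicate 1 or rrp6 replicate 2. The log2 fold change of R0010W ran from -9.59 to -6.29 over all alternatives. In total 1 feature was higher and 5 lower, and 314 had an unadjusted p under 0.05 where 377 would by chance. The higher count was 3 without WT replicate 1 or WT replicate 2, 4 with the replicate block, 12 with DESeq2 and 11 with the edgeR exact test. Library totals moved the median of all features to -0.18 and called 10 features lower.

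Lists that ranked differently between the double mutants, with no call ended by a left-out library, included box H/ACA snoRNAs, iron genes, early-terminated mRNAs, ribosomal protein genes and respiratory genes. Box H/ACA snoRNAs had a median of 0.84 (camera adjusted p = 5.8e-13; adjusted p = 0.4 with an estimated correlation) with 3 members higher adjusted over the list alone, and SNR9 stood at 65 ± 4 against 19 ± 1.4 CPM (1.77, adjusted p = 0.096, or 0.018 with the replicate block). Box C/D snoRNAs had a median of 0.40 (camera adjusted p = 4.5e-07; adjusted p = 0.61 with an estimated correlation). The Aft1 regulon, genes of iron uptake, had a median of -0.35 (camera adjusted p = 8.2e-08; adjusted p = 0.4 with an estimated correlation) with 2 members lower adjusted over the list alone, among them FIT2, a cell wall mannoprotein that retains iron siderophores, at -2.47 (adjusted p = 0.89, or 0.003 with the replicate block). The list of mRNAs controlled by early termination or the exosome had a median of -0.27 (camera adjusted p = 0.00017; adjusted p = 0.27 with an estimated correlation) with 3 members lower adjusted over the list alone, among them GSC2 at -1.51 (adjusted p = 0.097, or 0.016 with the replicate block). Ribosomal protein genes had a median of 0.30 (camera adjusted p = 2.2e-09; adjusted p = 0.59 with an estimated correlation) and nuclear respiratory genes a median of 0.37 (camera adjusted p = 1.1e-06; adjusted p = 0.4 with an estimated correlation). Ty element genes had a median of -0.31 (camera adjusted p = 2.2e-06; adjusted p = 0.59 with an estimated correlation), with YPRCTy1-4 at -1.77 (adjusted p = 0.49, or 0.029 with the replicate block), a copy whose reads may be shared with others. Single libraries moved these medians: without air1 rrp6 replicate 1 they were 0.49 for box H/ACA snoRNAs and -0.63 for the Aft1 regulon, and without air1 rrp6 replicate 2 they were 0.70 for box C/D snoRNAs, 0.18 for ribosomal protein genes and -0.16 for Ty genes. Without air2 rrp6 replicate 1 they were 0.13 for ribosomal protein genes and 0.24 for respiratory genes, and without air2 rrp6 replicate 2 the box C/D median was 0.84. Library totals moved the median of all features to -0.18, so the list medians with that scaling are to be read against this value. They were 0.16 for box C/D snoRNAs, 0.15 for ribosomal protein genes and 0.21 for respiratory genes. For early-terminated mRNAs the median was -0.49, for the Aft1 regulon -0.57 and for Ty genes -0.52. With the ribosomal DNA share as a covariate the medians were 0.46 for box H/ACA snoRNAs and -0.20 for Ty genes.

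The log2 fold changes of air1 rrp6 and air2 rrp6 against rrp6 had a correlation of 0.49 across features, which are not independent replicates. Counts simulated from the rrp6 means, without any change between strains, gave 0.50. The covariance was 0.104 against 0.102 in the simulations, a difference of 0.002. The comparisons shared 0 calls by edgeR's quasi-likelihood test, where simulations gave a mean of 0.1. Leaving out a library moved the correlation between 0.34 and 0.78, the latter without rrp6 replicate 2, and 0.34 was reached without air1 rrp6 replicate 2 and without air2 rrp6 replicate 2. The 2 rrp6 libraries were not split, and the observed correlation did not exceed the value from simulated unchanged groups with shared controls. The simulations held no replicate effect. With the replicate block the observed correlation was 0.48, and no blocked simulation was run beside it.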

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

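The tests of explanations in this part were all chosen after the result was seen, while the test of the difference between the double mutants was planned. That test (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) found 6 features for which the effect of losing AIR1 differed from the effect of losing AIR2. AIR2, at 3.77 on the log2 scale, and AIR1, at -6.48, are the deleted genes themselves. In the 2-micron plasmid, R0010W stood at -7.26, R0020C at -6.39 and R0040C at -6.37.

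These plasmid features were lower in both air1 rrp6 libraries than in any other library. A different scaling of the air1 rrp6 libraries would move all features alike. With library totals the median log2 fold change against rrp6 was 0.12 for all features and -6.77 for the plasmid list, which argues against scaling. Libraries of another strain under the air1 rrp6 labels are argued against by the label check above. The highest AIR1 level there was 2.39% of its lowest level elsewhere. Loss of the plasmid would lower all its features alike, and the log2 fold changes of these 3 features spanned 0.23 against rrp6, 0.85 against WT and 0.89 against air2 rrp6, with SEs of 0.40 to 0.67, so plasmid loss stays open. Whether the deletion of AIR1 or an event in this strain lies behind it cannot be told apart, because the design holds 1 strain without AIR1.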

How the results depend on the processing

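Of the alternative values of single named genes, 3340 were on the same side of the threshold, 39 passed it anew, 252 no longer passed and 3 reversed. With library totals 24 of 84 list medians changed sign, 22 of them against WT, under a scaling that moved the median of all features there to between 0.64 and 0.95. The alternatives chosen after seeing the data were WT replicate 2 thinned to the depth of replicate 1, the fit without ribosomal DNA features and the ribosomal DNA share as a covariate. Of 136 calls of named genes, 50 were lost with that covariate, 36 with library totals, and at most 26 when any single library was left out. Leaving out a library leaves its strain with 1 library, which is then assumed to vary like the other strains. A stricter threshold lowers counts by construction, while left-out libraries moved counts both ways, and for these and the other settings the cause was not tested. Of simulated 2-fold changes in features with a mean of at least 5 CPM, 29.5% were recovered. Among the named genes and lists given in the report, the replicate block changed no call other than those printed there, though it raised the higher box C/D snoRNAs in rrp6 from 4 to 6. Outside the report it ended the SNR4 call in air1 rrp6 against WT (adjusted p = 0.078) and moved the calls of some further genes and lists.

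With library totals in place of TMM, 1126 features were higher and 19 lower in rrp6 against WT, 1165 and 15 in air1 rrp6 against WT, and 1522 and 22 in air2 rrp6 against WT. Against rrp6, 2 were lower in air2 rrp6, 10 were lower in air1 rrp6 against air2 rrp6, and 15 lists passed in air1 rrp6 against WT. ADE12 at 0.06, VTC2 at 0.05 and HIS7 at 0.19 reversed in air2 rrp6 against WT with that scaling. DESeq2 called 158 features lower in rrp6 against WT, 188 lower in air2 rrp6 against WT, 3 higher and 9 lower in air1 rrp6 against rrp6, 1 higher and 20 lower in air2 rrp6 against rrp6, and 12 higher and 9 lower between the double mutants. The edgeR exact test called 173, 100 and 203 lower in rrp6, air1 rrp6 and air2 rrp6 against WT, 2 higher and 8 lower in air1 rrp6 against rrp6, 1 higher and 7 lower in air2 rrp6 against rrp6, and 11 higher and 12 lower between the double mutants. Limma-voom called 2 higher there.

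With the 2 strains compared alone, 310 were higher and 26 lower in rrp6 against WT, 240 and 27 in air1 rrp6 against WT, 420 higher in air2 rrp6 against WT, and 6 higher between the double mutants. With the ribosomal DNA share as a covariate, 311 were higher and 25 lower in rrp6, 104 and 14 in air1 rrp6, and 71 and 13 in air2 rrp6, each against WT. At an adjusted p under 0.01, these pairs were 294 and 22, 202 and 18, and 301 and 42. With a minimum fold of 2, 39 were lower in air1 rrp6 against WT. With the replicate block, 183, 126 and 197 were lower in rrp6, air1 rrp6 and air2 rrp6 against WT, and 4 were higher between the double mutants.

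Lists past camera's threshold numbered 11 in rrp6 against WT, 14 in air1 rrp6 and 11 in air2 rrp6 against rrp6, 16 between the double mutants, and 9 and 15 in air1 rrp6 and air2 rrp6 against WT. With an estimated correlation these counts were 0, 1, 0, 1, 2 and 0, and with fry 4, 1, 0, 1, 5 and 5. Over left-out libraries they ran from 11 to 17 in rrp6 against WT, 8 to 15 in air1 rrp6 and 7 to 16 in air2 rrp6 against rrp6, 12 to 26 between the double mutants, and 9 to 15 in air1 rrp6 against WT.

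Over left-out libraries, features lower in rrp6 against WT numbered 28 to 296, higher in air1 rrp6 against rrp6 0 to 12, lower in air2 rrp6 against rrp6 0 to 1, and higher between the double mutants 1 to 3. Against WT, air1 rrp6 had 204 to 546 higher and 19 to 63 lower, and air2 rrp6 had 299 to 641 higher and 37 to 150 lower. The correlation of the effects of both deletions against rrp6 ran from 0.34 to 0.78.

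Shares of counts rose by construction when rRNA and mitochondrial features left the total. In WT, rrp6, air1 rrp6 and air2 rrp6, CUTs then held 0.0639%, 0.522%, 0.426% and 0.497%, SUTs 0.274%, 0.541%, 0.524% and 0.553%, snoRNAs 1.99%, 3.29%, 2.51% and 1.83%, and 2-micron features 0.0642%, 0.065%, 0.000646% and 0.059%.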

Other observations

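The tests of explanations in this part were all chosen after the result was seen. Protein-coding genes outside the lists changed in the strains without RRP6. YJL047C-A, a short reading frame that met the naming rule in air2 rrp6 alone and was otherwise chosen after its values were seen, was higher than in WT by 5.25 on the log2 scale in rrp6 (adjusted p = 3.8e-05), 4.48 in air1 rrp6 (adjusted p = 0.0001) and 5.29 in air2 rrp6 (adjusted p = 4.5e-05). YNL040W was lower by log2 fold changes of -2.75, -2.63 and -2.46 in the same order. The neighbours of GYP5 did not pass the test in rrp6 against WT: RPL36B stood at 0.15 (adjusted p = 0.8), ATG41 at 0.50 (adjusted p = 0.54) and GAL4 at 1.08 (adjusted p = 0.15), while GYP5 itself had 224 and 778 counts in WT and 5 to 21 counts in each library without RRP6. The tRNAs had medians against WT of -0.82 in rrp6, -1.20 in air1 rrp6 and -1.56 in air2 rrp6, and without WT replicate 2, the library with 82.3% ribosomal DNA counts, these were 0.86, 0.22 and -0.39. In air2 rrp6 against WT, SNR9 fell by 2.14 (adjusted p = 0.0025), PHO12 fell by 1.89 (adjusted p = 0.00076) and RPL8A, a ribosomal protein gene with a near-identical copy, fell by 1.20 (adjusted p = 0.0042). These 3 calls ended with library totals.

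Box C/D snoRNAs had a median of -1.16 in air2 rrp6 against rrp6. The ribosomal DNA share of each library was taken as a stand-in for carry-over of RNA without a tail. It is an imperfect one, since TRAMP itself adds tails to RNAs and tailed RNA was selected. For the same reason, lower snoRNA counts do not tell fewer tails from less RNA. With that share as a covariate the median of tRNAs moved from -0.65 to 0.01, and the box C/D median was still -1.0 (SD over members 0.67). Adjusting by this share thus did not remove the box C/D shift. Carry-over itself is not excluded, since that SD is a spread between snoRNAs, not between libraries. The share may also vary with strain (62.9% ± 8.4 in rrp6 and 56.1% ± 1.4 in air2 rrp6). For box H/ACA snoRNAs carry-over stays open as well. Their median moved from -0.88 to -0.54 (SD 0.76), within 1 SD of 0, while the list still passed camera (adjusted p = 2.3e-09). A single rrp6 library does not account for the box C/D shift, since the box C/D median was -1.07 in the fit without an rrp6 library that came nearer to 0. SnoRNAs that move together between any libraries remain open, because with an estimated correlation the adjusted p was 0.31, and 2 libraries per strain cannot settle whether the loss of AIR2 or such joint movement lies behind the shift; these cannot be told apart.

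Of 10 leucine biosynthesis genes, 4 were lower than in WT in rrp6, 3 in air1 rrp6 and 4 in air2 rrp6, and the list did not pass with an estimated correlation (adjusted p = 0.09, 0.068 and 0.11). With library totals 3 members of the list (LEU1, OAC1 and BAT1) were still called lower in rrp6, so that scaling does not account for their fall. They are the genes that prompted the pattern. The list median moved to 0.09, below the median of all features with that scaling, 0.64. It was -0.52 with DESeq2 size factors and -0.42 with TMM from protein-coding genes. These values argue against scaling as the reason that the list lay below other features in rrp6. How far the list fell depends on the scaling. In the double mutants 2 members stayed in air1 rrp6 (LEU1 and OAC1, list median 0.08) and 1 in air2 rrp6 (LEU1, list median 0.46). Library totals moved the median of all features there to 0.78 and 0.95, above both list medians. With DESeq2 size factors the list medians were -0.66 and -0.45, and with TMM from protein-coding genes -0.56 and -0.37. Scaling is thus argued against for the place of the list below other features in the double mutants too, while the size of the fall depends on it. The count of members called lower with library totals replaced an earlier test on LEU1 alone, which pointed the same way for rrp6. Loss of RRP6 and the LEU2 marker, which restores a step of the leucine pathway, cannot be told apart, because 0 of the strains without RRP6 lack LEU2 reads.

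In the table deposited by the authors, the comparisons headed air1 and air2 over WT do not name rrp6 and were taken here as the double mutants. Their log2 ratios run opposite to the counts, with correlations across features of -0.87 and -0.88 with the fits above. The ratios of rrp6 against WT gave 0.89 and those of both double mutants against rrp6 gave 1.0. RRP6 stands there at 4.29 in a comparison of a double mutant with WT. With the sign of both double mutants' ratios turned, the ratios against WT followed WT replicate 1 alone, at 0.99, more closely than WT replicate 2, at 0.67 to 0.70, or the mean of both, at 0.93 to 0.94. After Benjamini-Hochberg adjustment of its p-values, that table gave 756 features in rrp6 against WT, 37 in air1 rrp6 and 44 in air2 rrp6 against rrp6, and 963 and 1139 in air1 rrp6 and air2 rrp6 against WT.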
